A study of Escherichia coli with 6 samples.

How the data were processed

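The series measured binding of MukB, TopA, ParC and RNA polymerase to the chromosome of Escherichia coli MG1655 by immunoprecipitation and sequencing, with 1 library per group and 6 libraries in all. Per the labels' protocols, sonicated cells were lysed, protein and DNA complexes were isolated with an antibody, and libraries were prepared for Illumina sequencing. The aligner, duplicate handling, genome build and peak calling are not given in the sources used here. Groups were taken from the sample titles.

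The files hold no header and 2 columns, a position on a 20-bp grid and a whole number. The values were treated as counts, as deposited, with no normalization known, because whole numbers with totals that differ between libraries do not contradict that unit. The lowest listed value was 6 in each library, and the number of positions went down up to a value of 11 and up again at 12 in each, so the deposited counts look like sums of smaller counts that each had a floor. This reading comes from the values and from no label. A position without a listed value is not a measured 0, and file totals are not sequencing depths.

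For each gene the listed counts over its 20-bp positions were divided by the number of positions. To set libraries side by side this value was multiplied by the 50 positions of a bin and divided by the library's median 1-kb bin, written as times the median bin. The median RNAP bin was 0, so RNAP is given in listed counts per position. Log2 ratios between MukB libraries used this scaling plus a pseudocount, the 5th percentile of scaled bins above 0, which was 0.169 for RIF to MukB, 0.28 for CA1 to MukB and 0.201 for RIF to CA1. Values of MukB with and without a treatment are relative within each library, since no spike-in was analysed here.

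Gene names and spans came from the table of assembly ASM584v2, with 4651 genes. The files name no build, so the match was checked with 38 genes of repeated insertion sequences, where fewer positions are listed: the share of missing positions was highest at a shift of 0 bp for MukB, TopA and ParC, −140 bp for RIF and −40 bp for CA1. RNAP was too sparse for this check. None of the table's coordinates are printed. The table has no strand, so the planned span with 200 bp upstream was replaced by 200 bp on both sides, and no genome sequence was used here, so the planned comparison inside and outside the matS sites was not run.

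Pairs of libraries were compared by Spearman's correlation over 4641 bins of 1 kb, with a 95% interval from 1000 resamples of 100-kb blocks and with 1000 rotations of one track around the circular chromosome. The comparisons, the 22 gene lists, with 455 genes of which 454 matched, and the rule for naming genes were fixed before the data were examined. That plan did not hold the classes of genes by RNAP counts or the correlations of log2 ratios with RNAP. Also outside it were the correlations of treated libraries with RNAP, the ratios of TopA and ParC to MukB and the comparison of ribosomal RNA copies. Each list's median was placed among 10000 random lists of the same size, for ratios matched in 20 strata of mean signal, and for levels also among 1000 rotations. The random lists drew single genes, the list's own members included, and rotations were not run for ratios. These percentiles describe the libraries and test no condition, and no p-value was computed. Shares of counts have exact binomial 95% intervals.

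Bins were placed by distance from oriC, taken midway between mnmG and mioC, in 10 parts per replichore, with intervals from resampled blocks of 20 bins. The rule named the 10 highest loci per library, where genes within 5 kb count as 1 locus, for RIF and CA1 against MukB the 10 largest positive and negative log2 ratios among genes above the median mean signal, the 2 highest and 2 lowest members of each list, and mukB, topA, parC, matP, rpoB and gyrA. Chosen after their values were seen were lacZ outside the RIF library, lacI, lacY, the genes named for RIF against CA1, and cyoA, seqA and trpT where they are quoted in a library whose rule did not name them. The alternatives tried were other bins, Pearson correlation, other scalings and pseudocounts, a filter on low genes, the highest position of a gene, random lists matched on length, and leaving out ribosomal RNA operons with 1 kb on either side.

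The calculations were tested on simulated libraries with a floor of 6 over the 4651 genes. Both libraries of a pair were drawn from the signal of MukB with CA1, with independent random counts and the floor set per base. Genes raised 4-fold read as a median log2 ratio of 2.85 at equal depth, and genes lowered 4-fold read as −3.03, so the floor can overstate differences. With the treated library at lower depth the values were 4.07 and −3.46, and at higher depth 2.19 and −2.63. Unchanged genes had a median of −0.04 at equal depth. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.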

Results

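Chromatin immunoprecipitation libraries of Escherichia coli MG1655, a wild-type K-12 laboratory strain, were compared, with 1 library in each of 6 groups. Cells were grown in LB medium at 37 °C with shaking at 200 rpm. In 5 libraries a FLAG-tagged protein was precipitated with an anti-FLAG antibody: MukB, the core subunit of the bacterial condensin, in untreated cells and after the treatments labelled RIF and CA1, TopA, which is topoisomerase I, and ParC, a subunit of topoisomerase IV. In the remaining library an antibody to RNA polymerase (RNAP) was used in cells without a tag. The labels do not spell out RIF or CA1. No difference below has a replicate check, since each group held 1 library, and no input or untagged library was analysed here.

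The deposited values were counts listed at 20-bp positions, with no listed value below 6. The listed counts summed to 5431344 in MukB, 1532672 in RNAP, 9224577 in TopA, 8856362 in ParC, 5170660 in MukB with RIF and 8527258 in MukB with CA1. These sums leave out everything below the floor and are not sequencing depths. Listed positions made up 60.2% of the chromosome in MukB, 4.58% in RNAP, 67.1% in TopA, 81.5% in ParC, 73.9% with RIF and 88.0% with CA1. Ribosomal RNA genes held 38.6% of the MukB counts (95% exact binomial interval 38.6 to 38.7), 56.4% of the RNAP counts (56.4 to 56.5), 35.7% in TopA (35.6 to 35.7) and 31.5% in ParC (31.5 to 31.6). The same genes held 2.07% of the counts with RIF (2.06 to 2.08) and 18.9% with CA1 (18.9 to 18.9). These intervals cover counting error only, and a listed count need not be an independent molecule.

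The first question was whether MukB lay where RNA polymerase lay, since the series concerns condensin at highly transcribed genes. MukB was highest at ribosomal RNA and tRNA loci. With genes within 5 kb taken as 1 locus, the highest loci were named by rrlG, a gene for large-subunit ribosomal RNA, at 346 times the median 1-kb bin, and by rrfF, at 342 times, followed by trpT, a tryptophan tRNA gene, at 318 times. All 22 ribosomal RNA genes, 82 of 86 tRNA genes and all 54 ribosomal protein genes were in the top 10% of genes in MukB, and 22, 85 and 54 were in the top 10% in RNAP. Among ribosomal protein genes rplQ and rpsD were highest in MukB, at 41.9 and 41.0 times the median bin, and rplY was lowest at 4.90 times. The copies of the large-subunit ribosomal RNA gene that run in reverse order, in rrnD and rrnG, averaged 2.42 times the other 5 copies in MukB, beside a ratio of 2.5 between the numbers of copies. The ratio was 2.36 in RNAP, 2.45 in TopA, 2.48 in ParC, 2.47 with CA1 and 6.63 with RIF. Values of single copies, rrlG and rrfF included, are therefore not read as separate measurements, and neither is their order. Some tRNA genes lie inside these operons, and repeats among the other tRNA genes were not examined.

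MukB was higher in each class of genes with more RNA polymerase. These classes were not part of the plan fixed before the data were examined. The 3492 genes with no listed RNAP position had a median of 0.711 times the median bin (quartiles 0.384 and 1.54). The median was 2.02 times in the 691 genes with up to 1 RNAP count per position, 3.42 times in 243 genes between 1 and 10, and 10.2 times in 76 genes between 10 and 100. In the 149 genes above 100, which include 22 ribosomal RNA and 80 tRNA genes, it was 45.4 times (quartiles 29.1 and 97.0). Over 4641 bins of 1 kb, Spearman's correlation between MukB and RNAP was 0.534 (95% block interval 0.473 to 0.598). None of 1000 rotations of one track around the chromosome reached this value, and the highest gave 0.288. Neighbouring bins are not independent replicates, and most bins had no RNAP listed. Both tracks were higher near oriC, and rotations shift this shared slope out of register. With MukB bins divided by the local median, chosen after seeing the data, the rank correlation was 0.463, and no rotations were run for it.

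**Figure D1:**
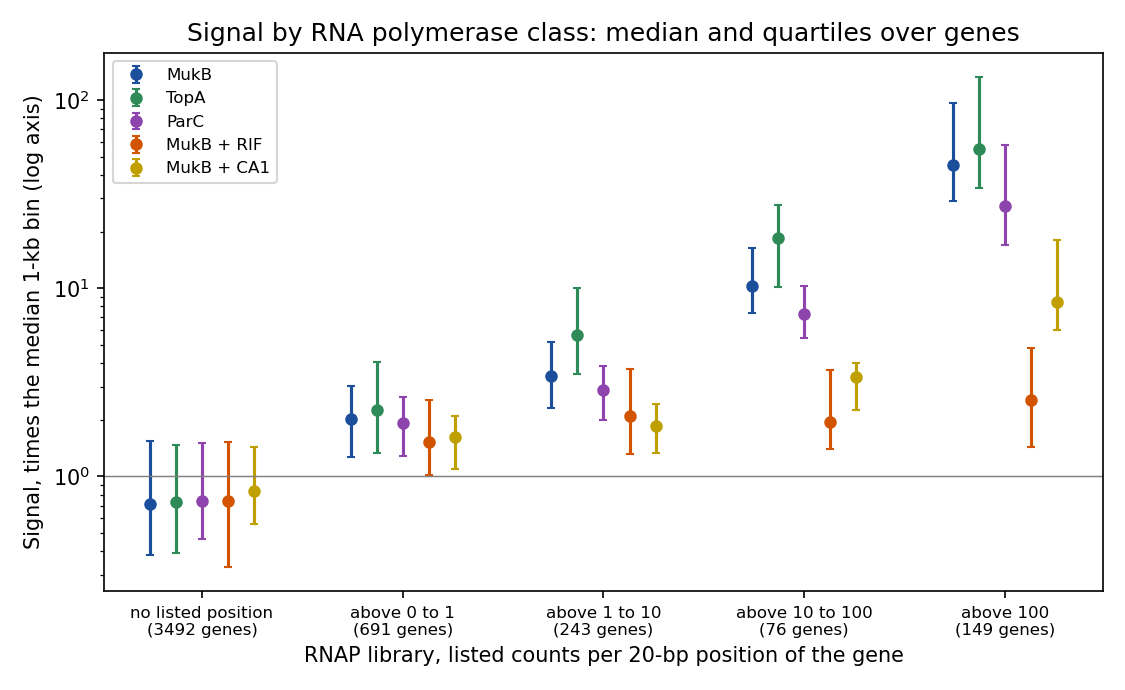
The plot shows the signal of the 5 anti-FLAG libraries in times the median 1-kb bin (log axis) for genes grouped by listed RNAP counts per position. Points are medians and bars are quartiles over genes, and in the class above 100 the medians were 45.4 for MukB, 55.2 for TopA, 27.3 for ParC, 2.53 with RIF and 8.45 with CA1.

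TopA, which relaxes negative supercoils, was likewise highest at ribosomal RNA and tRNA loci, with trpT at 213 times the median bin. Its highest listed value was at rrlG, at 379 times, which as a copy of a repeated gene is not a separate measurement. The protein-coding gene among its top 10 loci was the ribosomal protein gene rpmH, at 148 times. All 54 ribosomal protein genes and all 9 ATP synthase genes were in the top 10% of genes in TopA. The ATP synthase genes atpB and atpH were at 33.7 and 32.9 times the median bin. The rank correlation between TopA and RNAP over bins was 0.592 (0.538 to 0.635), and the highest of 1000 rotations gave 0.253. The median over genes went from 0.731 times the median bin without listed RNAP to 55.2 times above 100 RNAP counts per position.

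ParC, a subunit of the topoisomerase that unlinks daughter chromosomes, was highest at ribosomal RNA and tRNA loci, with trpT at 107 times the median bin. Its highest listed values were at rrlG, at 195 times, and at the isoleucine tRNA gene ileU, at 191 times, which both lie in reverse-order ribosomal RNA operons and are not separate measurements. In ParC all 22 ribosomal RNA genes, 84 of 86 tRNA genes and 53 of 54 ribosomal protein genes were in the top 10%. The ribosomal protein gene outside it was rpsA, at 3.11 times the median bin. The rank correlation between ParC and RNAP over bins was 0.553 (0.493 to 0.615), with 0.302 as the highest of 1000 rotations. The class medians went from 0.737 times without listed RNAP to 27.3 times above 100.

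TopA and MukB shared their highest loci and differed in genes of intermediate RNA polymerase. In genes between 10 and 100 RNAP counts per position the median log2 ratio of TopA to MukB was 0.63 (quartiles 0.23 and 0.99), and above 100 it was 0.22 (−0.01 and 0.36). These ratios used median scaling, the only scaling computed for this pair. The TCA cycle and cytochrome oxidase list stood at percentile 99.4 of 10000 random lists in TopA and at 28.4 in MukB, and at 91.1 and 45.7 among rotations, which keep neighbouring genes together. Its leading member cyoA, a subunit of cytochrome bo oxidase, was at 21.3 times the median bin in TopA and 2.32 times in MukB. The outer membrane proteins were at percentile 99.7 of random lists in TopA and 92.3 in MukB (99.8 and 87.1 among rotations), and the porin gene ompC was at 19.9 times in TopA and 6.85 times in MukB. The rank correlation between TopA and MukB over bins was 0.758 (0.703 to 0.801). Once each bin was divided by the median of its surroundings, an alternative chosen after seeing the data, the rank correlation was 0.515.

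ParC and MukB, whose proteins are known partners, had the highest rank correlation of the 5 pairs of untreated libraries compared here. Their top loci shared the names rrlG, trpT, rrfE, rrfA, rrfB, leuT and leuP. They also shared rrnD, named by rrfF in MukB and ileU in ParC, and rrnH, named by rrfH in MukB and rrsH in ParC. Repeated ribosomal RNA copies among these are not separate measurements. The rank correlation over bins was 0.958 (0.935 to 0.963), with 0.755 as the highest of 1000 rotations. After division of each bin by the median of its surroundings, chosen after seeing the data, the rank correlation was 0.719. Above 100 RNAP counts per position the median log2 ratio of ParC to MukB was −0.73 (quartiles −0.82 and −0.63). It was 0.05 in genes with no listed RNAP (−0.20 and 0.27). Median scaling was the only one computed for this pair.

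The next question was where MukB lay after the treatment labelled RIF. The ribosomal loci that led the MukB library were far lower relative to the rest of the chromosome. The median log2 ratio of MukB with RIF to MukB was −5.95 over 22 ribosomal RNA genes (quartiles −6.38 and −5.17), −4.88 over 86 tRNA genes (−5.67 and −3.42), −3.25 over 54 ribosomal protein genes (−3.65 and −2.53) and −2.38 over 9 ATP synthase genes (−2.62 and −2.26). All 22, 82 of 86, all 54 and all 9 members lay below 0. The 22 ribosomal RNA genes are repeated copies and not separate measurements, which also limits their place among random lists of distinct genes. Some tRNA genes lie inside ribosomal RNA operons, and without these operons the tRNA median was −4.44. Repeats among the other tRNA genes were not examined, so the place of the tRNA list can have the same limit. The tRNA gene trpT went from 318 times the median bin without RIF to 2.47 times with it, a log2 ratio of −6.92, and valZ from 49.9 to 0.306 times, a log2 ratio of −6.72.

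The highest RIF loci were others: lacZ at 60.2 times the median bin, the initiator tRNA gene metY at 27.7 times, the threonine tRNA gene thrW at 27.0 times, yshB at 21.8 times and the small RNA gene sokC at 19.7 times. Not all of these were higher than without RIF. In MukB without RIF lacZ was at 63.4 times, thrW at 14.0 times and yshB at 3.74 times. The lacZ plateau, which may not be chromosomal binding, is described below. The largest positive log2 ratios among genes above the median mean signal were at short genes: sokX at 3.63, rseD at 3.31, the small RNA gene glmY at 3.21, ybiI at 2.94 and timR at 2.60. Without RIF these genes had 2, 3.67, 9.8, 1.79 and 7.67 listed counts per position, in the same order. The size of such ratios depends on the floor and the pseudocount. The small RNA genes csrC and ryhB reached 19.8 and 15.8 times the median bin with RIF, and 12 of 16 small RNA genes were in the top 10%, against 8 in MukB.

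The other lists lay closer to the all-gene median with RIF than the ribosomal RNA, tRNA, ribosomal protein and ATP synthase lists did. Their order did not follow RNA polymerase throughout. The median RNAP count per position was 6.18 in small RNA genes and 0 in lipopolysaccharide synthesis. The medians were −1.42 for RNA polymerase and transcription factors, −1.13 for translation factors, −1.11 for lipopolysaccharide synthesis, −1.06 for outer membrane proteins and −0.85 for NADH dehydrogenase I. They were −0.82 for glycolysis, −0.63 for topoisomerases and condensin, −0.60 for the TCA cycle, −0.49 for cold shock and −0.44 for heat shock genes. Cryptic prophage genes were at −0.23, amino acid biosynthesis at −0.14, sigma S genes at −0.06, flagella and chemotaxis at 0.05, nucleoid-associated proteins at 0.06, small RNA genes at 0.07, acid resistance genes at 0.10 and catabolic operons at 0.11. Among genes matched on mean signal, the ribosomal RNA list was below all 10000 random lists, and the ribosomal proteins were at percentile 13.1, beside −2.70 for the median of matched lists. Matched lists could hold the list's own genes and those of the other ribosomal lists, so this median is not a neutral baseline. The tRNA, outer membrane and lipopolysaccharide lists were also below all 10000. ATP synthase and NADH dehydrogenase I were at percentile 0.02, the RNA polymerase list at 0.03, and the TCA cycle and glycolysis at 0.05. The random lists drew single genes, and rotations, which keep neighbouring genes together, were not run for ratios. For lists of neighbouring genes these percentiles can therefore look too extreme. In signal level with RIF, NADH dehydrogenase I was at percentile 3.71 among random lists but 28.2 among rotations.

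Over all 4651 genes, 243 were more than 2-fold higher with RIF and 563 more than 2-fold lower (1786 and 236 scaled to the total), and 42.4% had a log2 ratio of RIF to MukB above 0, with a median of −0.11, when each library was scaled to its median bin. Scaled to the total of listed counts, 85.0% were above 0 with a median of 0.82, and scaled to the upper quartile 54.0% were above 0 with a median of 0.05. Under total scaling the ribosomal RNA median was −4.81, the ribosomal protein median −2.12 and the tRNA median −3.82, while 9 of the negative lists were above 0: NADH dehydrogenase I at 0.10, glycolysis at 0.14, the TCA cycle at 0.22, cold shock at 0.31, topoisomerases and condensin at 0.36, prophage genes at 0.50, sigma S genes at 0.64, heat shock genes at 0.64 and amino acid biosynthesis at 0.68. With the upper quartile the sigma S genes alone had another sign, at 0.06. In simulated libraries with a floor of 6, genes lowered 4-fold read as a median log2 ratio of −3.03, so log2 ratios can overstate a difference. Of unchanged simulated genes 0.652% read as beyond 2-fold at equal depth, 11.8% with the treated library at lower depth and 0.989% at higher depth. The simulated pairs shared the same underlying signal, apart from the changed genes, and had no other variation between libraries than random counts and depth. These shares are therefore not rates of false calls for RIF against MukB. In 1159 genes with listed RNAP, the rank correlation between the log2 ratio and RNAP was −0.532, and over all 4651 genes it was −0.332. Genes with more RNAP were also higher in untreated MukB, the denominator of this ratio, so the correlation does not separate RNA polymerase from signal level. MukB with RIF had a rank correlation of 0.381 with RNAP over bins (0.320 to 0.443), against 0.534 in MukB. The highest of 1000 rotations gave 0.274. Its class medians went from 0.743 times the median bin without listed RNAP to 2.53 times above 100. The rank correlation between the 2 MukB libraries over bins was 0.865 (0.819 to 0.882), with 0.753 as the highest of 1000 rotations, and 0.428 after division by the local median.

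**Figure D2:**
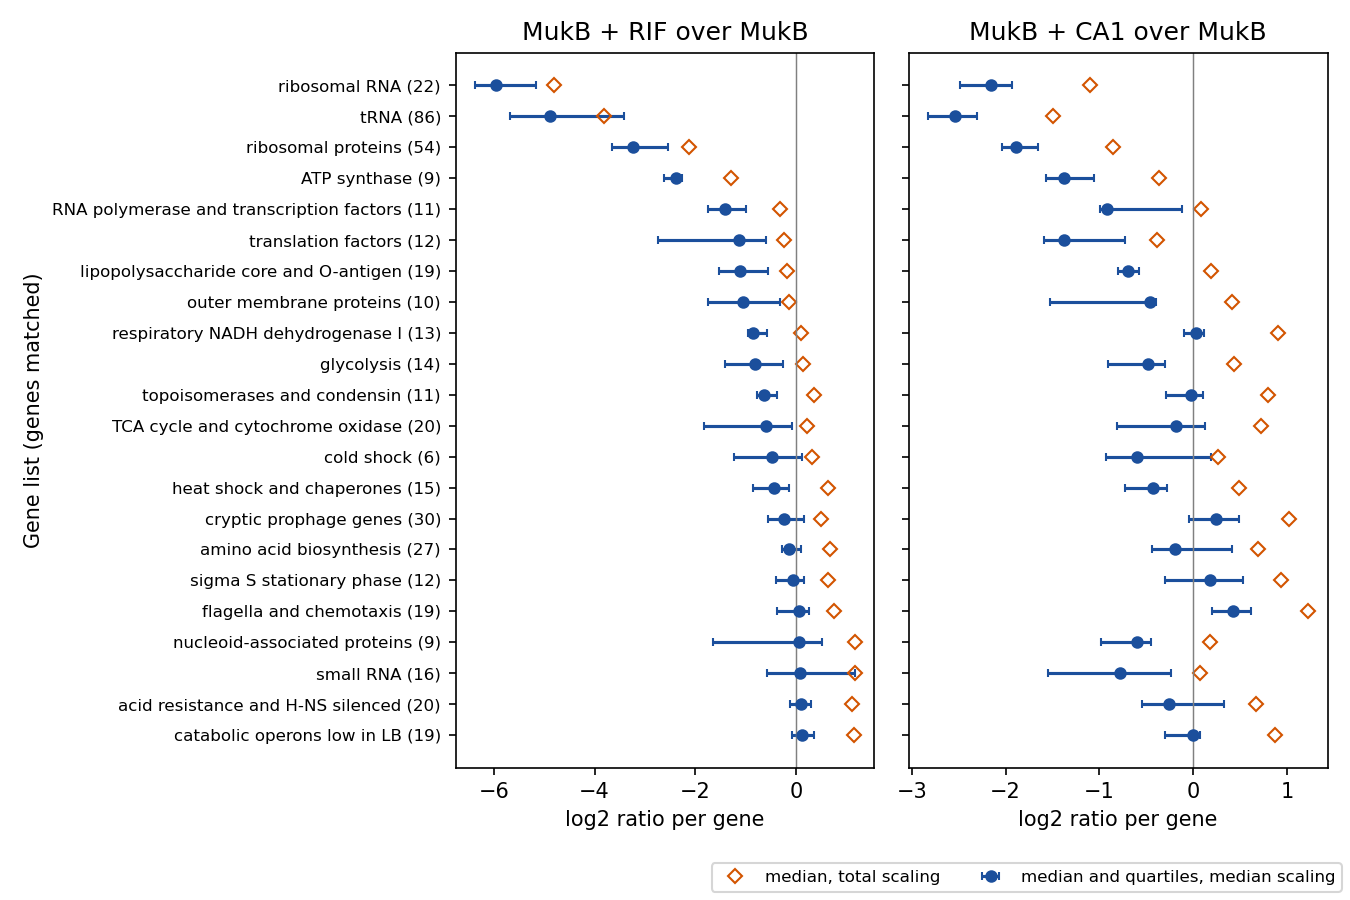
The plot shows the log2 ratio per gene to untreated MukB for 22 gene lists, with RIF on the left and CA1 on the right. Filled points and bars are medians and quartiles with median scaling and open diamonds are medians with total scaling, and ribosomal RNA genes lie at −5.95 and −4.81 with RIF and at −2.16 and −1.10 with CA1.

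After the treatment labelled CA1 the top 10 loci of MukB were ribosomal RNA and tRNA loci, at lower relative levels than without it. The median log2 ratio of MukB with CA1 to MukB was −2.54 over tRNA genes (quartiles −2.83 and −2.30), −2.16 over ribosomal RNA genes (−2.48 and −1.93), −1.89 over ribosomal protein genes (−2.04 and −1.66) and −1.38 over ATP synthase genes (−1.56 and −1.06). All 86, 22, 54 and 9 members lay below 0, where the 22 are again repeated copies. Without ribosomal RNA operons the tRNA median was −2.59, and repeats among the other tRNA genes were not examined. Among lists matched on mean signal, tRNA was below all 10000 random lists, while ribosomal RNA was at percentile 17.8 (matched median −2.02), ribosomal proteins at 90.1 (−1.95) and ATP synthase at 91.3 (−1.74). Matched lists could hold members of these same lists, so the matched medians are not a neutral baseline. Lipopolysaccharide synthesis was at percentile 0.01, cold shock at 0.1, translation factors at 1.09, nucleoid-associated proteins at 1.3 and the TCA cycle at 1.4. The top CA1 loci were gltW and ileU, tRNA genes inside the reverse-order ribosomal RNA operons and so not separate measurements, at 82.9 and 81.2 times the median bin, and trpT at 58.0 times. Among the lowest log2 ratios were the tRNA genes alaW at −3.23, lysZ at −3.23, metW at −3.22 and pheV at −3.15. Among genes above the median mean signal the highest log2 ratios were at xylZ at 0.96, the small RNA gene omrA at 0.87 and nanQ at 0.86.

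The other lists followed. With CA1 translation factors were at −1.38, RNA polymerase and transcription factors at −0.92, small RNA genes at −0.78, lipopolysaccharide synthesis at −0.69, nucleoid-associated proteins at −0.60, cold shock genes at −0.59, glycolysis at −0.48, outer membrane proteins at −0.46 and heat shock genes at −0.43. Acid resistance genes were at −0.26, amino acid biosynthesis at −0.20, the TCA cycle at −0.18, topoisomerases and condensin at −0.02, catabolic operons at −0.003, NADH dehydrogenase I at 0.03, sigma S genes at 0.18, prophage genes at 0.24 and flagella and chemotaxis at 0.42. Over all genes 78 were more than 2-fold higher with CA1 and 400 more than 2-fold lower (1827 and 122 scaled to the total), and 50.4% lay above 0 with median scaling (median 0.01), 90.5% with total scaling (median 0.88) and 64.3% with upper-quartile scaling (median 0.23). Under total scaling ribosomal RNA was at −1.10, ribosomal proteins at −0.86 and tRNA at −1.50, translation factors at −0.38 and ATP synthase at −0.36, and each other list was above 0: small RNA at 0.07, the RNA polymerase list at 0.08, nucleoid-associated proteins at 0.19, lipopolysaccharide synthesis at 0.19, cold shock at 0.27, outer membrane proteins at 0.42, glycolysis at 0.43, heat shock at 0.49, acid resistance at 0.67, amino acid biosynthesis at 0.69, the TCA cycle at 0.72, topoisomerases and condensin at 0.80 and catabolic operons at 0.87. With the upper quartile the TCA cycle (0.07), amino acid biosynthesis (0.05), topoisomerases and condensin (0.19) and catabolic operons (0.22) were above 0. The rank correlation over bins between MukB with CA1 and MukB was 0.932 (0.901 to 0.943), with 0.789 as the highest of 1000 rotations, and 0.58 after division by the local median. Between the log2 ratio and RNAP it was −0.739 over the 1159 genes with listed RNAP and −0.528 over all 4651 genes. Genes with more RNAP were also higher in untreated MukB, whose median bin was 339 listed counts against 1113 with CA1. This correlation therefore does not separate RNA polymerase from signal level. MukB with CA1 had a rank correlation of 0.451 with RNAP over bins (0.379 to 0.517), against 0.534 in MukB. The highest of 1000 rotations gave 0.304.

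The last comparison set the 2 treated MukB libraries side by side. Ribosomal RNA genes were lower with RIF than with CA1 by a median log2 ratio of −3.44 (quartiles −4.09 and −3.21), tRNA genes by −2.22 (−3.05 and −0.91) and ribosomal protein genes by −1.15 (−1.71 and −0.70). Small RNA genes were higher with RIF, with a median of 1.05 (0.72 and 1.88) and 15 of 16 above 0. Among genes above the median mean signal, the tRNA gene thrW was highest relative to CA1 at 3.89, followed by rirA at 3.34 and yjjY at 3.33, and gltU was lowest at −4.69. The ribosomal RNA, tRNA, ribosomal protein and small RNA lists had the same sign under each scaling. Over all genes 355 were more than 2-fold higher with RIF than with CA1 and 469 more than 2-fold lower, but 411 and 387 scaled to the total, 344 and 249 among genes above the 25th percentile of mean signal, 217 and 133 with 4 times the pseudocount, 637 and 306 with the highest position in the gene and 425 and 333 for the gene with 200 bp on both sides, a setting chosen after seeing the data, so which count is larger depends on the setting. Over all genes 39.2% were above 0 with median scaling, 42.8% with total scaling and 35.7% with the upper quartile. The rank correlation over bins was 0.862 (0.812 to 0.881), with 0.792 as the highest of 1000 rotations, and 0.307 after division by the local median. Both ratios to MukB contain the same MukB library, so the similarity of their lists is partly built in.

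Across the 22 lists, the median gene value lay above the central 95% of 10000 random lists for 8 lists in MukB, 12 in RNAP, 13 in TopA, 9 in ParC, 5 with RIF and 7 with CA1. Ribosomal RNA, ribosomal proteins, tRNA and small RNA were above it in all 6 libraries. With rotations in place of random lists, which keep operons together, the counts were 8, 12, 11, 7, 5 and 7, and the ribosomal proteins with RIF were at percentile 86.9. Translation factors were led by tufB, an elongation factor Tu gene, at 33.1 times the median bin in MukB, and the RNA polymerase list by rpoA at 40.5 times. The flagella and chemotaxis genes were among the lowest, with a median of 0.298 times the median bin in MukB and no member in the top 10% of any library. Their highest member in MukB was tsr, the serine chemoreceptor gene, at 2.63 times.

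Signal differed along the chromosome in each anti-FLAG library. The 10% of the chromosome nearest the replication origin oriC had a mean of 2169 listed counts per 1-kb bin in MukB and the farthest 10% had 113, a log2 ratio of 4.26 (95% block interval 2.90 to 5.21). The log2 ratio of nearest to farthest was 3.93 in TopA (2.80 to 4.87), 3.37 in ParC (2.46 to 4.13), 3.20 with RIF (2.93 to 3.52) and 2.62 with CA1 (2.10 to 3.17), and 5.33 in RNAP (2.60 to 9.16). With medians over bins it was 3.13 in MukB, 3.39 in TopA, 2.65 in ParC, 3.24 with RIF and 2.15 with CA1. Without ribosomal RNA operons, an alternative chosen after seeing the data, it was 3.13 in MukB, 3.25 in RNAP, 3.12 in TopA, 2.60 in ParC, 3.19 with RIF and 2.17 with CA1. Replication copy number was neither measured nor removed, since no input library was analysed here. The stretch of 652 kb from rrnE to rrnH, 14.1% of the chromosome, had a median of 1110 listed counts per bin in MukB, against 247 in the 200 kb after rrnH, and the log2 ratio was 2.17 in MukB, 1.03 in TopA, 1.79 in ParC, 2.03 with RIF and 1.37 with CA1. Against the 200 kb before rrnE it was 0.56 in MukB (0.21 to 0.84), −0.73 in TopA (−1.25 to −0.34), 0.13 in ParC (−0.08 to 0.31), 1.05 with RIF (0.75 to 1.31) and 0.27 with CA1 (0.07 to 0.44). The 200 kb after rrnH lie farther from oriC than the stretch and those before rrnE nearer, so both ratios contain any slope from oriC.

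**Figure D3:**
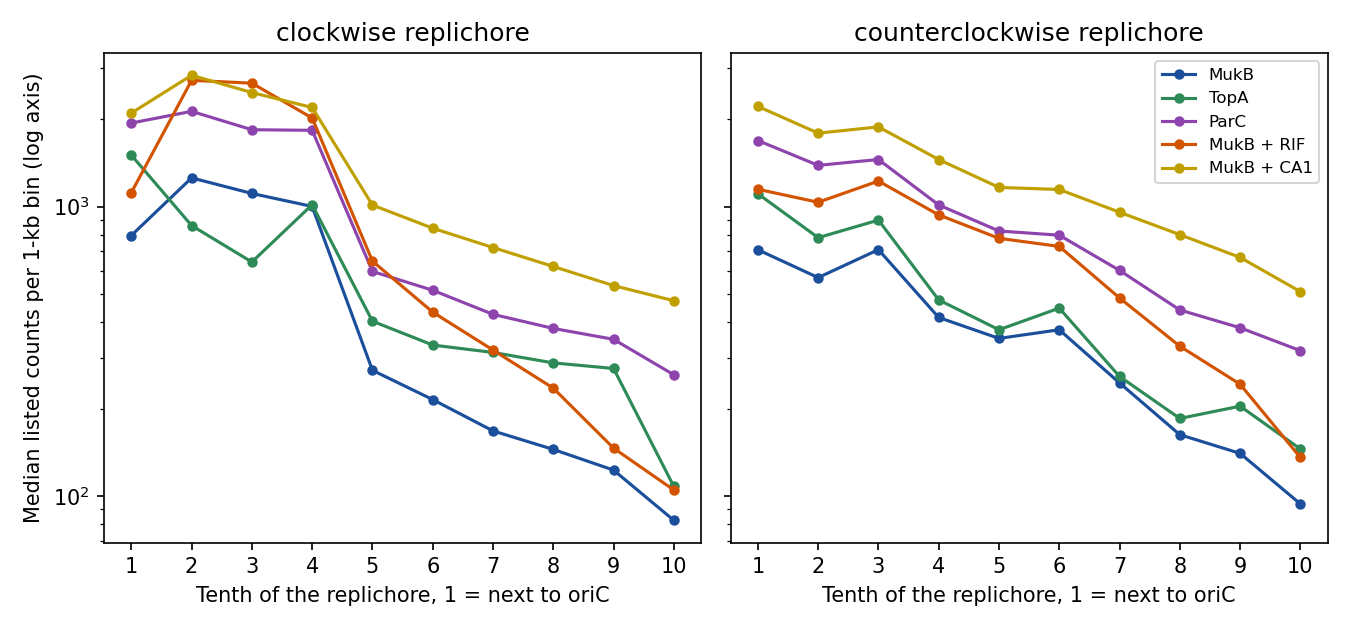
The plot shows the median listed counts per 1-kb bin (log axis) in 10 equal parts of each replichore, from oriC to the far end, for the 5 anti-FLAG libraries. In the clockwise replichore MukB lay at 1257, 1110 and 1001 in parts 2 to 4 and at 272 in part 5. In the counterclockwise replichore it lay at 568.5, 710 and 414 in parts 2 to 4 and at 350.5 in part 5.

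The lactose operon gene lacZ, for beta-galactosidase, stood out in every anti-FLAG library and not in RNAP. Its mean was 63.4 times the median bin in MukB, 48.6 in TopA, 35.9 in ParC, 60.2 with RIF and 13.3 with CA1. Unscaled, its median was 450 listed counts per position in MukB, 483 in TopA, 585 in ParC, 893 with RIF and 310 with CA1, and 0 in RNAP. The plateau reached 50% of this height at file positions 363240 and 366220 in all of them. A separate spike at 366480, in the neighbouring gene lacI, had 205 listed counts in MukB, 299 in TopA, 399 in ParC, 559 with RIF and 201 with CA1. In a running median of 3 positions, the first position under 10% of the plateau lay at most 20 bp beyond the first under 50%, against at least 80 bp at the other top loci of the same libraries. The neighbouring gene lacY had medians of 0, 0, 7, 13 and 15 in the same order, and lacI had 12, 8, 39, 65 and 24, with a mean of 77.9 with RIF, at percentile 95.9 of genes. Of the tagged genes themselves, mukB was at 0.766 times the median bin in MukB, topA at 2.19 times in TopA and parC at 1.46 times in ParC. The matP gene, for the organiser of the terminus region, was at 1.92 times, gyrA at 1.15 times and rpoB had 40.7 listed counts per position in MukB.

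**Figure D4:**
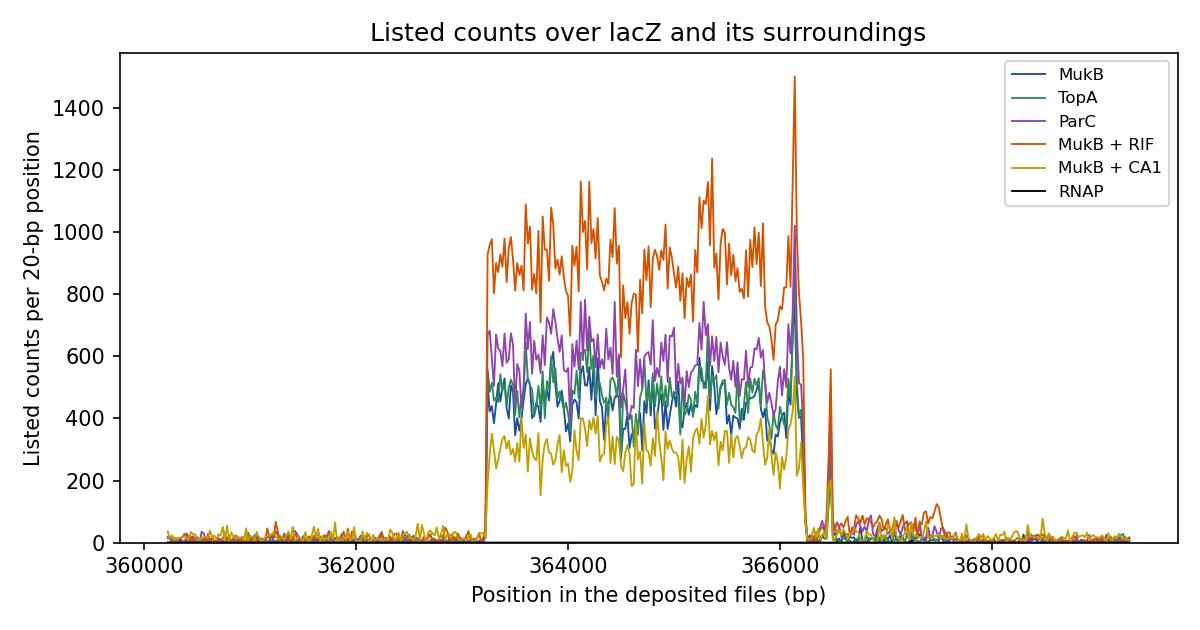
The plot shows listed counts per 20-bp position over lacZ and its surroundings, by position in the deposited files, for all 6 libraries. The 5 anti-FLAG libraries form a plateau between 363240 and 366220 with medians from 310 to 893, and RNAP lies at 0.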

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

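No paired analysis was possible because there is 1 library per group. Alternatives that need peak lists do not apply, and the matS comparison and the upstream span were not run. Dividing by the local median, leaving out the stretch from rrnE to rrnH, using only bins with RNAP, 200 bp on both sides of a gene, leaving out ribosomal RNA operons by distance from oriC and setting positions under 20 to 0 were tests chosen after seeing the data. Of the values under an alternative, 123 planned and 47 added ones stayed within the main interval, the main quartiles or 1.5 times the main count, while 55 planned and 26 added ones moved beyond it. No value given here changed sign, which covers ribosomal RNA, ribosomal proteins, tRNA, ATP synthase and, for RIF against CA1, small RNA. Other gene lists changed sign under total scaling. The cause was not tested for those that moved. The ribosomal RNA list has no value without its operons, and RNAP has no log2 ratio of medians by distance from oriC because its farthest median was 0.

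With 200 bp bins, the rank correlation was 0.422 for MukB against RNAP, 0.456 for TopA against RNAP, 0.434 for ParC against RNAP, 0.692 for TopA against MukB, 0.886 for ParC against MukB, 0.79 for MukB with RIF against MukB, 0.854 for MukB with CA1 against MukB, 0.797 for MukB with RIF against MukB with CA1. With 5 kb bins, the rank correlation was 0.666 for MukB against RNAP, 0.757 for TopA against RNAP, 0.678 for ParC against RNAP, 0.981 for ParC against MukB, 0.905 for MukB with RIF against MukB, 0.955 for MukB with CA1 against MukB, 0.916 for MukB with RIF against MukB with CA1. With Pearson's correlation on log2 values in place of Spearman's, it was 0.7 for MukB against RNAP, 0.723 for TopA against RNAP, 0.73 for ParC against RNAP, 0.97 for ParC against MukB, 0.776 for MukB with RIF against MukB, 0.947 for MukB with CA1 against MukB, 0.76 for MukB with RIF against MukB with CA1. With each bin divided by the local median, the rank correlation was 0.515 for TopA against MukB, 0.719 for ParC against MukB, 0.428 for MukB with RIF against MukB, 0.58 for MukB with CA1 against MukB, 0.307 for MukB with RIF against MukB with CA1. In pairs with RNAP the RNAP bins were left undivided, and the rank correlation was 0.463 for MukB against RNAP and 0.457 for TopA against RNAP. In bins with RNAP listed, the rank correlation was 0.633 for MukB against RNAP, 0.688 for TopA against RNAP, 0.633 for ParC against RNAP.

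Scaled to the total, the median log2 ratio was −4.81 (RIF over MukB ribosomal RNA), −2.12 (RIF over MukB ribosomal proteins), −1.29 (RIF over MukB ATP synthase), −1.10 (CA1 over MukB ribosomal RNA), −0.86 (CA1 over MukB ribosomal proteins), −1.50 (CA1 over MukB tRNA), −0.36 (CA1 over MukB ATP synthase). With positions under 20 set to 0, the median log2 ratio was −7.28 (RIF over MukB ribosomal RNA), −4.72 (RIF over MukB ribosomal proteins), −6.49 (RIF over MukB tRNA), −4.20 (RIF over MukB ATP synthase), −3.93 (CA1 over MukB ribosomal RNA), −3.66 (CA1 over MukB ribosomal proteins), −4.32 (CA1 over MukB tRNA), −3.15 (CA1 over MukB ATP synthase), −3.04 (RIF over CA1 ribosomal RNA). Scaled to the upper quartile, the median log2 ratio was −2.18 (RIF over MukB ATP synthase), −1.88 (CA1 over MukB ribosomal RNA), −1.62 (CA1 over MukB ribosomal proteins), −2.26 (CA1 over MukB tRNA). With the pseudocount 4 times as large, the median log2 ratio was −2.07 (RIF over MukB ATP synthase). With the highest position in the gene, the median log2 ratio was −1.90 (RIF over MukB ATP synthase), −2.93 (RIF over CA1 ribosomal RNA).

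For RIF over MukB, 243 genes were more than 2-fold higher, against 1786 scaled to the total, 112 with 4 times the pseudocount, 880 with positions under 20 set to 0. For RIF over MukB, 563 genes were more than 2-fold lower, against 236 scaled to the total, 360 with 4 times the pseudocount, 949 with the highest position in the gene, 1364 with positions under 20 set to 0. For CA1 over MukB, 78 genes were more than 2-fold higher, against 1827 scaled to the total, 193 scaled to the upper quartile, 196 with a smaller pseudocount, 1 with 4 times the pseudocount, 21 among genes above the 25th percentile, 43 with the highest position in the gene, 14 for the gene with 200 bp on both sides, 1187 with positions under 20 set to 0. For CA1 over MukB, 400 genes were more than 2-fold lower, against 122 scaled to the total, 836 with the highest position in the gene, 1570 with positions under 20 set to 0. For RIF over CA1, 355 genes were more than 2-fold higher, against 217 with 4 times the pseudocount, 637 with the highest position in the gene, 853 with positions under 20 set to 0. For RIF over CA1, 469 genes were more than 2-fold lower, against 716 with a smaller pseudocount, 133 with 4 times the pseudocount, 249 among genes above the 25th percentile, 306 with the highest position in the gene, 1514 with positions under 20 set to 0. Log2 ratios of genes near the floor are limited by depth.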

Other observations

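The tests of the stretch from rrnE to rrnH, of lacZ and of the genes with the most RNA polymerase were chosen only after the results were seen. In MukB the genes for topoisomerases and condensin were led by gyrB, a DNA gyrase subunit gene, at 2.68 times the median bin, and topA was lowest at 0.406 times. In TopA the same list was led by seqA, whose product sequesters newly replicated DNA, with 10.2 times the median bin against 1.22 times in MukB and 1.07 times in ParC. Cryptic prophage genes had list medians of 0.562 times the median bin in MukB and 0.439 times in TopA, and dicB, a cell division inhibitor gene, had no listed position in TopA. Their percentiles were 1.75 and 0.01 among random lists but 22.8 and 6.1 among rotations.

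The stretch of 652 kb from rrnE to rrnH, 14.1% of the chromosome, was higher than the 200 kb after rrnH by a log2 ratio of 2.17 in MukB (95% block interval 1.90 to 2.37), 1.79 in ParC, 2.03 with RIF, 1.37 with CA1 and 1.03 in TopA, while against the 200 kb before rrnE it was 0.56 in MukB, 0.13 in ParC (−0.08 to 0.31), 1.05 with RIF, 0.27 with CA1 and −0.73 in TopA. Both ratios contain any slope from oriC, since these neighbours lie farther from it and nearer to it. Parts 3 and 4 of the clockwise replichore lie in the stretch. Their median bins were 1110 and 1001 in MukB, beside 710 and 414 in the same counterclockwise parts. With RIF they were 2668 and 2023 beside 1225 and 936, and in TopA 643.5 and 1015 beside 898 and 476. ParC and CA1 were also higher clockwise in both parts. A difference in depth acting through the floor stays open, since the excess after rrnH was larger the lower the median bin in 4 libraries, and TopA alone departed from this order, with ParC above it by 0.761 (0.41 to 1.24). Extra copies of the stretch in some cultures could give a step up at rrnE as large as the step down at rrnH, and the steps at rrnE were −0.02 in MukB (−0.50 to 0.79), 0.17 in ParC (−0.56 to 0.50), 0.95 with RIF (−0.08 to 1.21) and 0.25 with CA1 (−0.04 to 0.44), beside −1.86, −1.74, −1.94 and −0.96 at rrnH. TopA had −1.08 (−2.12 to −0.34) at rrnE and −0.84 at rrnH. In MukB, ParC, RIF and CA1 steps of up to 2.69, at rrnD in MukB, were seen at other ribosomal RNA operons, so local signal beside an operon can hide a step up at rrnE, although with RIF the largest was 0.84, at rrnA, and hiding is less easily argued there. Extra copies, and binding of MukB and ParC along the whole stretch, with 2.17 in MukB, cannot be told apart without an input library.

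The plateau over lacZ had abrupt ends. From the first position under 50% of its height to the first under 10%, in a running median of 3 positions, was at most 20 bp in the 5 anti-FLAG libraries, while at the other top loci of the same libraries the shortest such distance was 80 bp. Protein bound along lacZ on sonicated chromosomal DNA is argued against by these widths, since sonication ends lie at random. A candidate explanation is DNA whose ends lie in or beside lacZ, such as a cloned copy, and whether it came from the tagged strains or from another sample was not tested. RNAP, from cells without a tag, had no listed value over lacZ, but it listed only 4.58% of positions.

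MukB, TopA and ParC were all high at the 149 genes with the most RNA polymerase. Sequence, mapping or copy number shared by all libraries is argued against, because with RIF the upper quartile of the log2 ratio to MukB over these genes was −2.04 even under total scaling. A transcription-linked background of the FLAG antibody could also make the libraries alike, and the median log2 ratio over these genes was 0.22 for TopA to MukB but −0.73 for ParC to MukB (quartiles −0.82 and −0.63). Both used median scaling, the only scaling computed for these pairs. That scaling depends on the floor, so the difference between the 2 ratios decides nothing. Ribosomal RNA genes held 38.6% of the listed counts in MukB, 35.7% in TopA and 31.5% in ParC. The amount of such background in each library was not measured, so without a library from an untagged strain it cannot be told apart from shared binding, which remains a hypothesis.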
